A study of Mus musculus with 6 samples.

How the data were processed

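The 6 samples were RNA from 4T1ch9 cells transduced with lentivirus carrying a non-targeting or an STC1 shRNA. Per the labels' protocols, RNA was extracted with a spin-column kit and checked by capillary electrophoresis, and biotinylated cRNA was prepared for Illumina bead arrays. Groups were taken from the labels: non-targeting (2 arrays, given 6 and 18 µl of virus, numbered as replicates 1 and 2), STC1 shRNA with 6 µl (2 arrays) and STC1 shRNA with 18 µl (2 arrays). No chip, slide position, scan date or batch was given in the sources used here, so none could be entered in a fit.

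The deposited table of unprocessed values holds a linear bead intensity for each probe and array, not normalised between arrays per the file headers. A detection p-value for each probe and array stands beside it, per the file headers, and its values are multiples of 1 over 936, as from a ranking against 936 negative control probes. The deposited processed table holds log2 values whose scale and normalisation the labels do not state. Set against the raw values, each of its columns equalled the quantile-normalised log2 of the raw intensity to a median absolute difference of at most 0.0002, and each had a median of 5.777, so scale and array order were settled by this comparison. The scanner software and its version were not given in the sources used here. No column of values was left without a sample.

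The intensities were background-corrected and normalised with neqc of limma 3.58.1 in R 4.3.3, which takes the background from the negative controls implied by the detection p-values, adds an offset of 16, quantile-normalises and takes log2. Quantile normalisation gives all arrays the same distribution, so a change of most transcripts in the same direction would be removed. The offset draws small values together, so folds of dim probes are understated. Probes with a detection p-value under 0.05 on at least 2 of the 6 arrays were tested, which left 18076 of 45281. Gene symbols came from the platform annotation, updated through gene identifiers with a reference table of the mouse genome. It listed 34903 probes, 34885 with 1 symbol and 18 with several, and 34807 gene identifiers matched. The other 10378 probes were unnamed here. Of the tested probes 15408 named 9754 genes and 2668 named no single gene. Where a gene had several tested probes, the probe with the highest mean log2 intensity stood for it, and other probes that did not pass are given for the changed genes named. No genome coordinates were used.

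Differences were tested with limma's lmFit and eBayes on log2 intensities. The model had 1 mean for each of the 3 groups, so that the arrays shared an estimate of the spread with 3 residual and 5.66 prior degrees of freedom. Contrasts were the mean of both STC1 groups minus non-targeting, each STC1 group minus non-targeting, and STC1 at 18 µl minus STC1 at 6 µl. A model with 1 mean for each virus and volume gave the difference between the STC1 effects at 18 and 6 µl. Tests were two-sided with Benjamini-Hochberg adjustment over the probes tested, and changed means an adjusted p under 0.05. A fold is 2 to the power of the log2 difference. Where a probe was not above background on any array of a group, only a bound is given: the mean log2 of the brighter group against a mean over the dim group's arrays of the higher of the lowest signal above background and the probe's own signal.

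Named genes followed a fixed rule: Stc1 and Stc2, then the 12 genes with the largest rise and the 12 with the largest fall among genes that passed and whose 4 STC1 arrays all lay beyond both non-targeting arrays. Clone names were skipped. For comparisons where under 3 genes passed each way, the 5 each way with the smallest p were named as values. For each gene list the up to 4 members with the smallest p were named, and further list members are named where a count is spelled out. The 22 lists covered stanniocalcins, calcium and phosphate handling, uncoupling and antioxidant defence, hypoxia, oxidative phosphorylation, the unfolded protein and ATF4 response, interferon response, inflammatory and NF-kB targets, mitosis, DNA replication, p53 targets, epithelial and mesenchymal markers, matrix proteases and metastasis-associated genes, angiogenesis, ERK targets, YAP and TEAD targets, sterol biosynthesis, cytosolic ribosomal proteins, and markers of fibroblasts, leukocytes and endothelium. The 18 lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry. The groups, tests, gene lists, naming rule and all alternatives but the crossed pairing were chosen before the data were examined.

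The procedure was tested on simulated data with the real probes' means, their spreads as estimated by eBayes and the design of STC1 against non-targeting, over 18076 probes of which 200 were changed. It recovered 36% of probes changed by 0.5 on the log2 scale and 100% of those changed by 1, 1.5 or 2. Of 187 calls 19 were false. Over 20 further simulations the mean share of false calls was 6.92%, above the nominal share. With no change simulated there were 0 calls. In a test of 40 simulated lists a shifted list was called and 0 unshifted lists were. Probes were simulated independently, so this does not show how often lists whose genes vary together are called falsely. Nor does it show the share of false probe calls where an array differs from the others over many probes. The estimated correlation in the real data reached 0.59, for the sterol list.

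Alternatives were no background correction with an offset of 50, the authors' processed log2 values, median scaling, no filter on dim probes, detection on all 6 arrays, 1 probe per gene, the replicate number as a block, virus volume as a covariate, 2 groups only, eBayes with trend and robust settings, array weights, a 2-fold threshold and each array left out in turn. Where an array left out leaves 1 array in a group, that array is assumed to vary like the others. For comparisons that share the non-targeting arrays, the correlation and covariance of their log2 differences were set against 100 simulations with no effect. The overlap of their calls was set against independent lists only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.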

Results

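Gene expression was measured in 4T1ch9 cells, a clone of the mouse mammary carcinoma line 4T1, after lentiviral delivery of a short hairpin RNA (shRNA) against Stc1 or of a non-targeting shRNA. Stc1 encodes stanniocalcin 1, a secreted glycoprotein first known as a regulator of calcium in fish. Transduced cells were selected with puromycin for 5 to 6 days, and total RNA was hybridised to 6 Illumina bead arrays. The non-targeting virus was represented by 2 arrays, 1 given 6 µl and 1 given 18 µl of virus. The STC1 virus was represented by 2 arrays at 6 µl and 2 at 18 µl. Mean raw signal per array ranged from 228.3 to 310.6, and between 16252 and 17507 of the 45281 probes were above background on each array. Across the 18076 tested probes, Pearson's r was 0.9931 between the 2 non-targeting arrays, 0.9939 between the 2 STC1 arrays at 6 µl and 0.9914 between the 2 STC1 arrays at 18 µl, where probes are not independent replicates. No 2 arrays held identical values. The sources used here do not say whether arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every comparison.

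The first question was whether the STC1 hairpin lowered its target. Stc1 fell in all 4 arrays of the STC1 virus, to 2.54-fold below the non-targeting level (log2 difference -1.35, SE 0.14, 95% interval -1.67 to -1.03, limma adjusted p = 0.0025, n = 4 against 2). Its normalised log2 intensity was 9.05 and 9.32 on the non-targeting arrays given 6 and 18 µl. It was 7.68 and 7.87 on the STC1 arrays at 6 µl and 8.05 and 7.74 on those at 18 µl. The difference was -1.41 at 6 µl (adjusted p = 0.00923) and -1.29 at 18 µl (adjusted p = 0.00736). Stc1 remained above background on all 6 arrays. A second Stc1 probe was below background on all 6 arrays and gave no level. Stc2, the related stanniocalcin, differed by -0.14 (SE 0.12, adjusted p = 0.526), so of this 2-member list 1 gene fell, both over all genes and adjusted over the list alone.

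**Figure D1:**
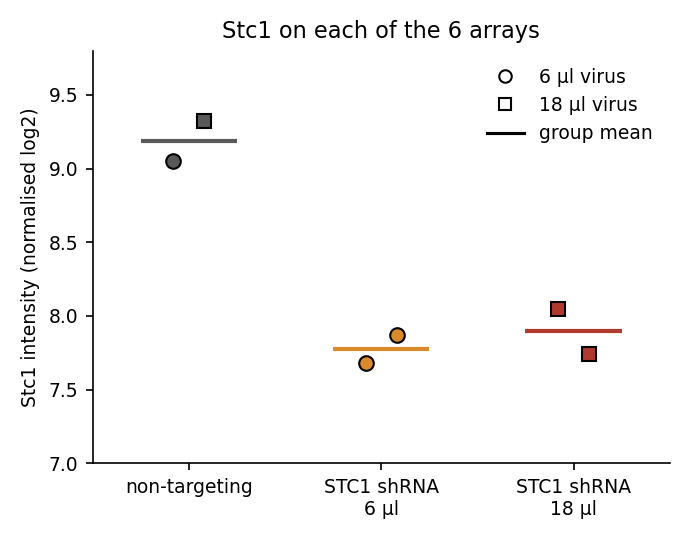
Normalised log2 intensity of Stc1 (vertical axis) in the 3 groups (horizontal axis), with 1 point per array, circles for 6 µl and squares for 18 µl of virus, and a line at each group's mean. The 4 STC1 shRNA arrays lay between 7.68 and 8.05, below both non-targeting arrays at 9.05 and 9.32.

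The broadest question was which transcripts differed between cells given the STC1 hairpin and cells given the non-targeting one. The largest rise was in Ccl9, a chemokine, which was 4.81-fold higher (log2 difference 2.26, SE 0.14, adjusted p = 0.000401, n = 4 against 2). The largest fall was in Tmsb10, thymosin beta 10, an actin-binding peptide, which was 8.84-fold lower (log2 difference -3.14, SE 0.14, adjusted p = 4.1e-05). Its 2 further probes were called the same way, at -3.15 and -0.93, so the size of the fall differed between probes. Slco4a1, an organic anion transporter, was 5.37-fold lower (-2.42, SE 0.19, adjusted p = 0.000856). In all, 1407 of 18076 probes passed the threshold, 688 higher and 719 lower. These covered 434 genes that rose and 363 that fell, of which 48 rose and 51 fell by at least 2-fold.

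Among other genes with large rises were Bdh2, a cytosolic hydroxybutyrate dehydrogenase (3.21-fold), Rnase4, a secreted ribonuclease (3.19-fold), Mustn1, a nuclear protein of musculoskeletal tissue (3.05-fold), and Camk2n1, an inhibitor of calcium/calmodulin-dependent kinase II (2.98-fold). Slc24a3, a sodium, potassium and calcium exchanger, rose 2.74-fold, Phactr1, a regulator of phosphatase 1 and actin, 2.66-fold, and Slc44a3, a choline transporter-like protein, 2.55-fold. Apol9a, an apolipoprotein L, rose 2.5-fold and Syngr3, a synaptic vesicle protein, 2.49-fold. Inmt, an N-methyltransferase, and Fam180a were not above background on either non-targeting array and were at least 2.71-fold and at least 2.35-fold higher. SEs of these log2 differences lay between 0.11 and 0.27, and their adjusted p-values between 0.00114 and 0.0147. A second probe did not pass for Inmt (0.32) or for Phactr1 (-0.22). Rnase4, Phactr1, Slc44a3 and Apol9a did not pass without non-targeting replicate 1 (adjusted p between 0.0507 and 0.0628) or without non-targeting replicate 2 (0.0515 to 0.0915), nor did Bdh2 without non-targeting replicate 2 (0.0571) or Phactr1 without STC1 6 µl replicate 2 (0.058).

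Large falls were also seen in Mycbp, a MYC-binding protein (3.49-fold), Bloc1s1, a subunit of lysosome-related complexes (3.42-fold), and Eif4ebp1, a repressor of cap-dependent translation (3.35-fold). Sri, the calcium-binding protein sorcin, fell 3.24-fold, Polr3k, a subunit of RNA polymerase III, 3.06-fold, Chac1, a glutathione-degrading enzyme, 2.9-fold, and Entpd6, a nucleotidase, 2.87-fold. The glutathione transferases Gsta1 (3.48-fold) and Gsta2 (3.29-fold) and the proliferin Prl2c2 (3.08-fold) also fell. These 3 genes and Apol9a have near-identical relatives, so which family member each probe read is uncertain. Of 2 further Mycbp probes 1 was called lower (-1.72) and the other was at 0.17. The SEs of these falls lay between 0.11 and 0.32 on the log2 scale. Chac1 did not pass without non-targeting replicate 1 (adjusted p = 0.0618) or 2 (0.0524), nor Prl2c2 without STC1 6 µl replicate 1 (0.0521) or 2 (0.0763) or STC1 18 µl replicate 2 (0.0695). The 2 non-targeting arrays differed for Prl2c2 (7.69 and 6.26), whose log2 difference was -0.92 without replicate 1 and -2.34 without replicate 2. Ordered by size, Stc1 was number 22 among the genes that fell, and 21 genes fell by more. Without non-targeting replicate 1 Stc1 was at -1.49 and 11 of these 21 still fell by more, with Prl2c2 not among them. Without non-targeting replicate 2 Stc1 was at -1.21 and all 21 fell by more. With no background correction, 15 of the 24 largest log2 differences shrank by over 1.5 times, as did 5 with the authors' values, and all 24 kept their sign. The order around Stc1 then changed. With no background correction Gsta2 (-1.01), Prl2c2 (-0.77) and Entpd6 (-0.53) fell by less than Stc1 (-1.08). With the authors' values Entpd6 (-0.86) fell by less than Stc1 (-1.22).

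**Figure D2:**
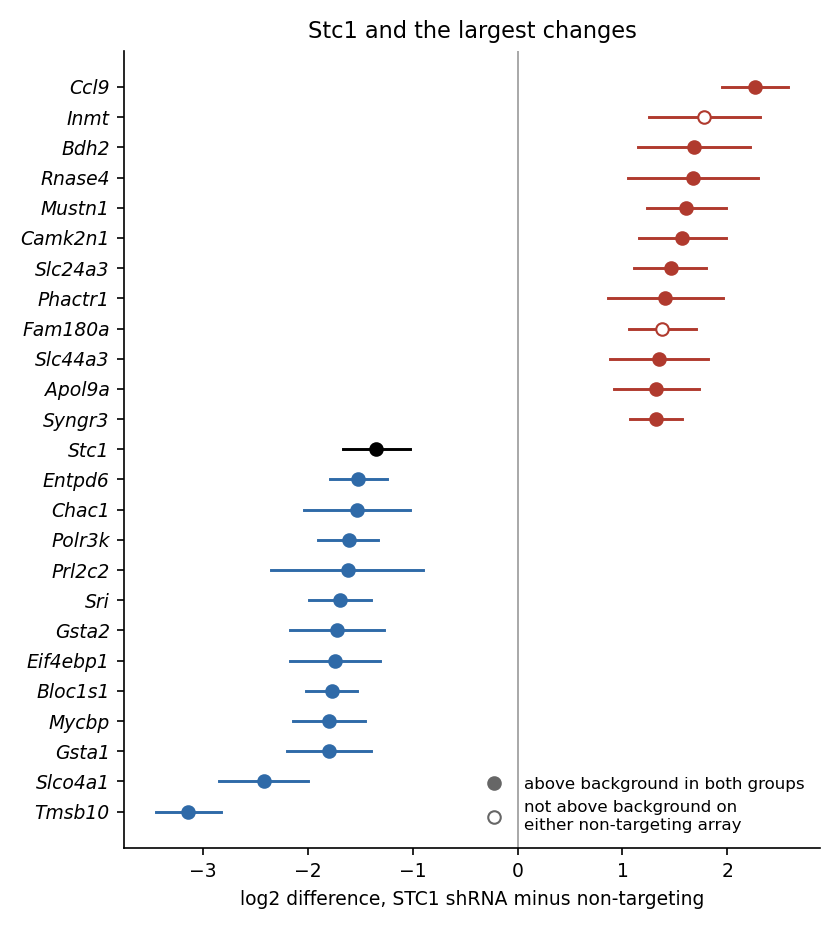
Log2 difference between STC1 shRNA and non-targeting arrays (horizontal axis) for Stc1 and the 12 genes with the largest rise and the 12 with the largest fall (vertical axis), with lines for the 95% interval and open points for genes not above background on either non-targeting array. Intervals run from -3.45 to -2.83 for Tmsb10 and from 1.95 to 2.58 for Ccl9.

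Of the 1407 probes, 1401 had all 4 STC1 arrays on one side of both non-targeting arrays. The same arrays had selected these probes, so this count gives no separate support. Over all tested probes the share separated in this way was 35.4%, where chance gives 13.3%. Of 320 changed genes with another tested probe, 133 had another probe called the same way and 2 had one called the opposite way. The count was 155 without non-targeting replicate 1, 207 without non-targeting replicate 2, 699 and 321 without STC1 6 µl replicates 1 and 2, and 681 without STC1 18 µl replicate 2. With median scaling in place of quantile normalisation 2528 probes passed, 80.8% of them higher against 48.9% in the main setting, and the median log2 difference of all tested probes was 0.149 against 0.014.

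Of 21 tested interferon-response genes 7 rose, none fell and 14 did not pass, or 10 rose and 0 fell adjusted over the list alone. The list was higher by camera (adjusted p = 0.000312), but not with an estimated correlation (adjusted p = 0.356) or by fry (adjusted p = 0.0628). Ifit2 (2.27-fold, log2 difference 1.18, SE 0.11), the guanylate-binding protein gene Gbp2 (2.29-fold), Oasl2 (2.11-fold) and Parp14 (1.83-fold) led the list, whose median log2 difference was 0.42. The median was 0.27 without STC1 18 µl replicate 2, 0.24 with the authors' values, 0.18 with no background correction and 0.12 with no filter on dim probes, and the list passed camera at the preset correlation in each. The list's mean stood at -0.29 and -0.28 relative to the mean of the 6 arrays on the non-targeting arrays. It was 0.17, 0.17 and 0.24 on 3 STC1 arrays and -0.01 on STC1 18 µl replicate 1.

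Of 28 tested genes of the unfolded protein and ATF4 response 4 fell, none rose and 24 did not pass, or 9 fell and 0 rose adjusted over the list alone. The list was lower by camera (adjusted p = 0.00112) and by fry (adjusted p = 0.0233), but not with an estimated correlation (adjusted p = 0.234). The 4 were Chac1, Pdia4, a protein disulphide isomerase of the endoplasmic reticulum (2.12-fold lower, -1.09, SE 0.14), the transcription factor gene Xbp1 (1.61-fold lower) and Phgdh, the first enzyme of serine synthesis (1.6-fold lower). The list's median was -0.11, or 0.02 with median scaling, which is -0.13 relative to the shift of all probes. It was -0.17 without STC1 6 µl replicate 1. Of 21 tested matrix proteases and metastasis-associated genes 6 fell, none rose and 15 did not pass (7 fell and 0 rose adjusted over the list alone). This list was also lower by camera (adjusted p = 0.00112) and by fry (adjusted p = 0.0107), but not with an estimated correlation (adjusted p = 0.234). The stromelysin genes Mmp3 (2.53-fold lower, -1.34, SE 0.13) and Mmp10 (2.26-fold lower) fell the most, with Plaur (1.61-fold), Plat (1.57-fold), Cd44 (1.5-fold) and Itga6 (1.42-fold). The list's median of -0.21 was -0.12 with the authors' values, -0.08 with no background correction, -0.05 with no filter on dim probes and -0.13 with median scaling or detection on all 6 arrays.

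Hypoxia-response genes were divided. Of 24 tested members 4 fell and 1 rose (8 and 1 adjusted over the list alone). Pfkl, a glycolytic enzyme, was 1.83-fold lower, the glucose transporter gene Slc2a1 1.55-fold lower, and P4ha1 and Ankrd37 were 1.46-fold and 1.61-fold lower. Vegfa, the vascular growth factor, was 1.77-fold higher (0.82, SE 0.14). The list was lower by camera (adjusted p = 0.00942), but not with an estimated correlation (adjusted p = 0.672) or without non-targeting replicate 2 (adjusted p = 0.179).

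ERK targets, antioxidant genes and replication genes were lower by camera with larger p-values. Of 19 ERK signalling targets 3 fell (2 rose and 6 fell adjusted over the list alone): Epha2 was 2.02-fold, the phosphatase gene Dusp5 2.01-fold and the growth factor gene Hbegf 1.75-fold lower, and Etv4 was at -0.51 (adjusted p = 0.053). The camera test gave adjusted p = 0.046, and adjusted p = 0.528 with an estimated correlation. The call was lost without non-targeting replicates 1 and 2 (adjusted p = 0.0616 and 0.0754) and without STC1 18 µl replicate 2 (0.0626). Of 20 genes of uncoupling and antioxidant defence 3 fell, also adjusted over the list alone: the cystine transporter gene Slc7a11 (2.55-fold, -1.35, SE 0.13), Txn2 (1.95-fold) and Hmox1 (1.7-fold). The log2 difference of Hmox1 was -0.77, or -0.47 without non-targeting replicate 1 and -0.42 with the authors' values. With no background correction it was -0.26 and did not pass (limma adjusted p = 0.0607). Txnrd2 was at -0.41 and did not pass. Here camera gave adjusted p = 0.0465, and adjusted p = 0.528 with an estimated correlation. The call was lost without non-targeting replicate 1 (adjusted p = 0.149), STC1 6 µl replicate 1 (0.0555) or STC1 18 µl replicate 1 (0.21), without the filter on dim probes (0.125), with detection on all 6 arrays (0.0592) and with 2 groups only (0.0554). Of 31 DNA replication genes only Tk1 fell by the probe standing for each gene (1.54-fold), also adjusted over the list alone, with Mcm3 at -0.51, Rrm2 at -0.43 and Tyms at -0.31. The other Rrm2 probe was called lower (-0.63), as was 1 of 3 further Tyms probes, which ranged from -0.61 to 0.11. This list had adjusted p = 0.0371 by camera and adjusted p = 0.8 with an estimated correlation. That call was lost without non-targeting replicate 1 (adjusted p = 0.299), without STC1 18 µl replicate 2 (0.123) and with median scaling (0.232). With median scaling the medians of the antioxidant and replication lists were 0.11 and 0.08, which are -0.04 and -0.07 relative to the shift of all probes.

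**Figure D3:**
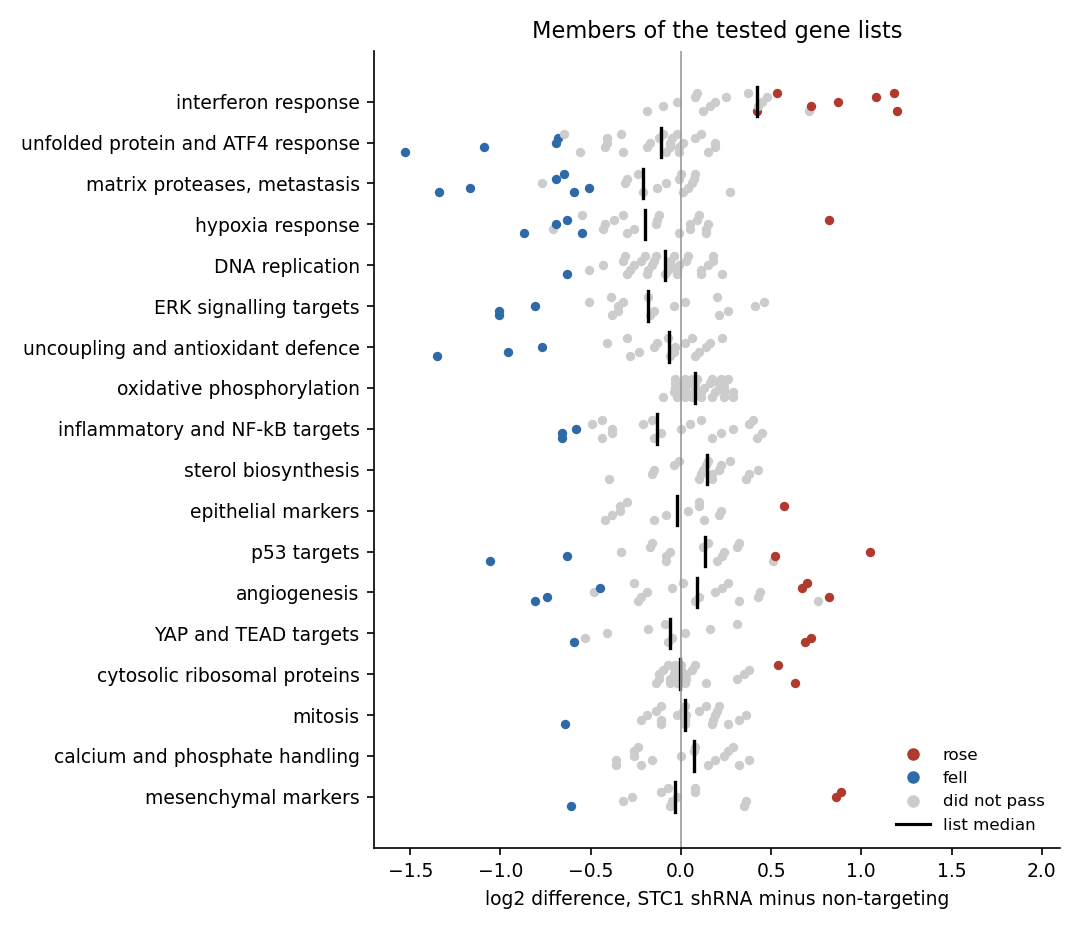
Log2 difference between STC1 shRNA and non-targeting arrays (horizontal axis) for each tested member of the 18 gene lists with at least 5 tested members (vertical axis, ordered by camera adjusted p), red for members that rose, blue for members that fell, grey for the rest, and a black bar at each list's median. The interferon list has its median at 0.42 and the matrix list at -0.21.

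The remaining lists did not pass the camera test in the main setting. None of the 17 tested genes of calcium and phosphate handling changed, also adjusted over the list alone. The nearest was the phosphate exporter gene Xpr1 (0.38, SE 0.11, adjusted p = 0.0748), followed by Itpr2 (0.29), Atp2c2 (-0.36) and Trpc1, which was not above background on either non-targeting array. The list had median 0.07, mean 0.01 and a camera direction of lower (adjusted p = 0.941), with a median of -0.02 relative to the shift of all probes under median scaling. Its median had no settled sign: it was -0.04 without non-targeting replicate 1, -0.03 without STC1 18 µl replicate 1, -0.05 with detection on all 6 arrays and 0.16 without STC1 18 µl replicate 2. Inflammatory and NF-kB targets had 3 of 22 members lower, Vcam1 (1.58-fold), Il23a (1.58-fold) and Tnfaip2 (1.49-fold), with camera adjusted p = 0.116, or 3 higher and 7 lower adjusted over the list alone, and Nfkbia was at -0.49 (adjusted p = 0.0573). Of 22 angiogenesis genes 3 rose and 3 fell (5 and 3 adjusted over the list alone): besides Vegfa, Angpt1 rose 1.63-fold and Pdgfc at least 1.44-fold (not above background on either non-targeting array), while Angpt2 fell 1.67-fold (camera adjusted p = 0.749). Of 18 p53 targets the death receptor gene Fas (2.07-fold) and Bbc3 (1.43-fold) rose, and the cell cycle inhibitor gene Cdkn1a (2.09-fold) and Ei24 (1.55-fold) fell (3 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.749). Of 12 YAP and TEAD targets Nuak2 (1.62-fold) and Ccn2 (1.64-fold) rose and Amotl2 (1.51-fold) fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.749), and Ankrd1 was at -0.53 (adjusted p = 0.0546). Ccn2 went from 0.72 to 0.43 without non-targeting replicate 2 and did not pass (adjusted p = 0.194).

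Epithelial and mesenchymal markers showed no shared direction. Of 14 tested epithelial markers only St14, a membrane protease, rose (not above background on either non-targeting array, at least 1.23-fold, camera adjusted p = 0.637), with Esrp2 at -0.42, Tjp1 at -0.38 and Spint1 at -0.34. St14 went from 0.57 to 0.33 with the authors' values. With no background correction it was at 0.18 and did not pass (limma adjusted p = 0.105). Of 14 mesenchymal markers the matrix genes Col6a1 (1.86-fold) and Fn1 (1.81-fold) rose and Col5a1 fell (1.53-fold), with list median -0.03, mean 0.08 and a camera direction of higher (adjusted p = 0.942). Cdh2 did not pass and was not above background on either non-targeting array. The counts of both lists were the same adjusted over the list alone, as were those of the next 4 lists. Of 23 mitosis genes only the kinase gene Aurka fell (1.56-fold, camera adjusted p = 0.861), with Prc1 at 0.32, Cenpf at 0.36 and Nusap1 at 0.26. A second Cenpf probe was called higher (0.49). None of 37 oxidative phosphorylation genes or of 18 sterol biosynthesis genes passed (camera adjusted p = 0.0913 and 0.371, and adjusted p = 0.8 and 0.892 with an estimated correlation). The smallest p-values were those of Ndufv1 (0.29), Cox7a2 (0.29), Ndufv2 (0.24) and Cox6b1 (0.24) in the first list and of Sc5d (0.43), Ebp (0.36), Hsd17b7 (0.38) and Lss (-0.40) in the second. At the preset correlation, the oxidative phosphorylation list was higher by camera with no background correction (adjusted p = 0.0159), the authors' values (0.0451), no filter on dim probes (0.0109) and trend and robust settings (0.0239), and the sterol list without non-targeting replicate 2 (0.0132) or STC1 18 µl replicate 2 (0.0238). An estimated correlation was not run in these settings. Of 26 cytosolic ribosomal protein genes Rpl22 (1.55-fold) and Rplp0 (1.46-fold) rose, with list median -0.01, mean 0.07 and a camera direction of higher (adjusted p = 0.749), and Rpl14 was at 0.38 and Rps25 at 0.35. With single arrays left out the mesenchymal median ran from -0.07 (without STC1 18 µl replicate 1) to 0.09 (without non-targeting replicate 1) and the ribosomal from -0.01 to 0.03 (without STC1 6 µl replicate 1). Relative to the shift of all probes under median scaling, the mesenchymal and ribosomal medians were -0.04 and -0.02, and unadjusted for it 0.11 and 0.13.

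Markers of other cell types were mostly not above background. Of 12 fibroblast markers 2 were tested and Pdgfrb, a growth factor receptor gene, rose (at least 1.48-fold, not above background on either non-targeting array), while Pdgfra was at 0.35 and did not pass. Of 14 leukocyte markers 4 were tested and of 10 endothelial markers 2 were tested, and none of these changed, with Cd14 at 0.03 (SE 0.15), Coro1a at -0.04, Eng at -0.00 (SE 0.14) and Kdr at 0.11. Cd3e and Csf1r were not above background on either non-targeting array. Counts for these 3 lists were the same adjusted over the list alone.

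Over the gene lists, 52 members changed. Of these, 6 passed without non-targeting replicate 1, 8 without non-targeting replicate 2, 32 and 16 without STC1 6 µl replicates 1 and 2, and 45 and 32 without STC1 18 µl replicates 1 and 2. Of 22 with another tested probe, 9 had another called the same way and 0 the opposite way. No other probe passed for Pfkl (-0.30), Vcam1 (-0.40), Il23a (-0.17), Tk1 (-0.47), Ei24 (-0.39), Cd44 (-0.47 and -0.30) or Itga6 (-0.24 and -0.01) among the genes that fell, nor for Fas (0.28), Angpt1 (0.28), Gbp3 (0.52) or Rplp0 (0.16) among those that rose. Other probes stood on the opposite side of 0 for P4ha1 (0.10) and, for 1 of 2, Bbc3 (-0.02 and 0.28), and 1 of 2 for Fn1 did not pass (0.24). The 79 named genes outside the 24 largest changes include genes that had not passed in the main setting and had no call to lose. Of those that had passed, 3 lost their call with no background correction, 9 with median scaling and 17 without the filter. With no background correction these were St14 (0.18), Pdgfc (0.20) and Hmox1 (-0.26). Tnfaip2 (-0.38), Ei24 (-0.41) and Cd44 (-0.38) were among those lost with median scaling.

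The next question was whether the effect was seen at each virus volume. Each STC1 volume was set against both non-targeting arrays, 1 given 6 µl and 1 given 18 µl. The reference was thus not matched by volume. At 6 µl Tmsb10 differed by -3.08 (adjusted p = 0.000166) and Ccl9 by 1.85 (adjusted p = 0.00265) on the log2 scale, with n = 2 arrays against 2 in the limma fit. At 18 µl the values were -3.21 (adjusted p = 0.000117) and 2.68 (adjusted p = 0.000438). Ifit2 rose by 1.09 and 1.28 (adjusted p = 0.00971 and 0.00378) and Mmp3 differed by -1.30 and -1.38 (adjusted p = 0.00862 and 0.00389) at 6 and 18 µl. At 6 µl 691 probes passed, 362 higher and 329 lower, and at 18 µl 717 passed, 304 higher and 413 lower. Both comparisons called 171 probes as higher and 237 as lower, where independent lists of these sizes would share 6.09 and 7.52. The log2 differences had Pearson's r of 0.80 across probes (0.50 in 100 simulations with no effect and shared controls) and a covariance of 0.084 (0.013 simulated). Part of the excess over independent lists may come from the shared non-targeting arrays. With a separate volume-matched non-targeting array for each comparison, r was 0.62 and the covariance 0.072.

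Without non-targeting replicates 1 and 2 the count was 62 and 52 at 6 µl and 92 and 180 at 18 µl. Without STC1 6 µl replicates 1 and 2 it was 30 and 18 at 6 µl and 332 and 292 at 18 µl, and without STC1 18 µl replicates 1 and 2 it was 393 and 89 at 18 µl. With median scaling 2985 probes passed at 6 µl, 91.3% higher against 52.4% in the main setting, and 971 at 18 µl, 56% higher against 42.4%.

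A direct comparison asked whether 18 µl of STC1 virus differed from 6 µl. Stc1 differed by 0.12 (SE 0.16, adjusted p = 0.92). Ccl9 differed by 0.83 (SE 0.16) and Ttyh2 by -0.90 (SE 0.14), and neither passed in limma (adjusted p = 0.434 for both). The other genes with the smallest p-values, Proc (0.70), Exosc3 (0.67), Slc37a3 (0.67) and Sag (0.68) above, and Slc5a3 (-0.81), Tmem164 (-0.81), Pou5f2 (-0.80) and Baiap2 (-0.88) below, also had adjusted p = 0.434. No probe passed, while 1230 had an unadjusted p under 0.05. Sterol biosynthesis genes had a median difference of 0.45 between volumes (camera adjusted p = 4.27e-12, and adjusted p = 0.903 with an estimated correlation), and hypoxia genes of 0.22 (camera adjusted p = 0.000117, and adjusted p = 0.903 with an estimated correlation). For both lists the arrays of a group stood apart: the mean of the sterol genes relative to all 6 arrays was 0.50 on STC1 18 µl replicate 1 and 0.06 on replicate 2, and that of the hypoxia genes 0.12 and -0.03. On the non-targeting arrays given 6 and 18 µl the sterol mean was -0.24 and 0.09 and the hypoxia mean 0.04 and 0.24. Both lists were thus also higher at 18 µl with the non-targeting virus, on 1 array per volume. Without STC1 18 µl replicate 1 the median difference was 0.31 for the sterol genes (camera adjusted p = 0.000102) and 0.11 for the hypoxia genes, which then did not pass (camera adjusted p = 0.085). Without STC1 18 µl replicate 2 the sterol median was 0.76, and without STC1 6 µl replicate 1 the hypoxia median was 0.08. With median scaling 121 probes passed, 5 higher and 116 lower, with a median shift of all probes of -0.164, and without STC1 6 µl replicate 2 there was 1, which has no gene name here.

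The last comparison asked whether the STC1 effect depended on virus volume, with the volume-matched non-targeting array as the reference at each volume. Stc1 had a difference between effects of -0.15 (SE 0.28) and Tmsb10 of -0.16 (SE 0.29), both with limma adjusted p = 1. The smallest p-values were those of Nuak1 (-1.93), Fkbp14 (-1.76), Gpr135 (-1.14), Wdr25 (-1.29) and Utrn (-1.21) on the lower side and of Sppl2c (1.34), Ift57 (1.42), Nr5a2 (1.35), Tapbp (1.11) and Polr3c (1.18) on the higher side, with SEs between 0.24 and 0.33 and adjusted p = 1 for each. No probe passed, and 773 had an unadjusted p under 0.05. The non-targeting virus had 1 array per volume, which was assumed to vary like the STC1 arrays. With median scaling the probes of Nuak1 (-2.05, SE 0.35, adjusted p = 0.00186) and Fkbp14 (-1.84, SE 0.36, adjusted p = 0.0173) passed, where all probes shifted by a median of -0.282, and without STC1 6 µl replicate 2 there was 1 probe, which has no gene name here.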

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

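The tests of explanations in this part were chosen after the patterns were seen. Each named gene, each tested list's mean and 2 measures per array were searched for a single STC1 array far from the other 3, in 124 items. Chance flags about 1 in 20 groups, or 6.2 items here, and 10 were found. STC1 18 µl replicate 1 was the array set apart in 6 of them. On that array Phactr1 was lowest, with a gap of 0.962 of the range of the 4 arrays (6.76 against 7.75 to 7.79), as were the interferon-response genes Gbp2 (0.887 of the range) and Oasl2 (0.838), and Plaur was highest (0.891). The mean of the antioxidant list (0.836) and of the epithelial list (0.854) were also lowest there. On STC1 6 µl replicate 2 Aurka was highest (0.863) and Eng lowest (0.909), and on STC1 18 µl replicate 2 Bbc3 (0.855) and the mean of the angiogenesis list (0.923) were highest. No named gene had both STC1 arrays above both non-targeting arrays at 1 volume and both below them at the other.

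STC1 18 µl replicate 1 also had the largest loading, -0.817, on the second principal component (20.3% of the variance), and had the highest sterol biosynthesis genes of the 6 arrays. Whether a dim array accounts for this stays open: the array had the fewest probes above background, 16252, while its mean and median raw signals of 253.6 and 53.32 lay above those of non-targeting replicate 1 (228.3 and 52.11). RNA from non-targeting cells mixed into the sample is argued against for the sterol genes, because a mixture would lie between its sources, while 16 of 18 were higher there than on any other array and the list's median stood at 0.51 relative to the mean of the 6 arrays, against at most 0.13 elsewhere. The STC1 effect on this array was smaller: its slope on the mean of the other 3 STC1 arrays was 0.74, over 1434 probes called without it. Those 3 had slopes of 0.87 to 1.08, each over the 321 to 699 probes called without that array. A mixture with non-targeting RNA is argued against here too. The probes that fell would need a median share of 0.11 of such RNA and those that rose 0.41, a difference of 0.31. On the other STC1 arrays this difference was at most 0.11. The probe sets differ between arrays, so neither the slopes nor these differences compare the same probes. The sterol median was also higher on the other arrays given 18 µl (0.13 non-targeting, 0.07 STC1) than on those given 6 µl (-0.23 non-targeting, -0.22 and -0.17 STC1). What sets this array apart stays open, and no biological explanation was tested.

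A further pattern was that 21 genes fell by more than Stc1, the gene the hairpin was made for. Without non-targeting replicate 1 Stc1 was at -1.49 and 11 of the 21 still fell by more. Without non-targeting replicate 2 Stc1 was at -1.21 and all 21 did. The order depends on processing: with no background correction Stc1 was at -1.08, and Gsta2 (-1.01), Prl2c2 (-0.77) and Entpd6 (-0.53) fell by less. A fault of single probes is argued against as the cause of the direction, for the 9 of the 21 genes with another tested probe. All 9 had another probe called as lower (for Mycbp 1 of 2), and the remaining 12 had none. The size is less settled. Another probe also fell by more than Stc1 (-1.35) for Tmsb10 (-3.15), Mycbp (-1.72), Gsta1 (-1.67), Sri (-1.45) and Polr3k (-1.62). The only other probe of Prl2c2 (-0.67) and of Slc7a11 (-0.51) did not. Neither did the remaining probe of Tmsb10 (-0.93), Sri (-1.28) or Mycbp (0.17). Brighter STC1 arrays are argued against by 23 genes chosen as falling by more than Stc1 on non-targeting replicate 1 and the STC1 6 µl arrays alone, 18 of them among the 21: on the arrays not used to choose them, of nearly equal raw brightness, their median difference from non-targeting replicate 2 was -1.43 and -1.51 on the STC1 18 µl arrays. Whether the hairpin also lowered some of these transcripts directly cannot be told apart from a consequence of the loss of Stc1, because the labels name no second STC1 hairpin and no hairpin sequence was used here. Virus volume does not help, as the 21 genes differed by a median of -0.04 between 18 and 6 µl and Stc1 itself by 0.12 (SE 0.16).

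The third pattern weighed was the higher interferon list, for which leukocytes in the cultures were considered. Of the 5 abundant leukocyte transcripts Ptprc, Cd74, Lyz2, Tyrobp and Laptm5, 0 were detected on 2 or more STC1 arrays and 1 on a single STC1 array. These 5 were picked after the filter on dim probes had left them out, so they give no separate test. Of the 4 tested leukocyte markers, Cd14 and Coro1a were above background on all 6 arrays and did not pass the test. Cd3e (0.20) and Csf1r (0.18) were above background on STC1 arrays only and did not pass either. Whether a few leukocytes were present stays open. Array brightness is argued against by a median difference of the interferon list of 0.32 and 0.36 between each STC1 18 µl array and non-targeting replicate 2. A larger volume of virus is argued against, since both STC1 arrays given 6 µl lay above the non-targeting array given 18 µl, by a median of 0.43 and 0.46, where the list mean had an SD of 0.13 between STC1 arrays of 1 volume. The titre of each virus was not given in the sources used here, so a difference in particles per volume may remain, as may a response to this hairpin's sequence or to the loss of Stc1, none of them tested.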

How the results depend on the processing

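The crossed pairing below was the alternative chosen after seeing the data. Stc1 fell and passed under every alternative run, between -1.08 and -1.49 (adjusted p from 1.92e-06 to 0.0253). Of the 24 largest changes, all passed with no background correction, the authors' values and median scaling, and Rnase4, Phactr1 and Prl2c2 did not without the filter on dim probes. With detection on all 6 arrays 4 of them were not tested. The interferon, unfolded protein and matrix lists passed camera at its preset correlation in 16 settings, but not with an estimated correlation (adjusted p = 0.356, 0.234 and 0.234). For STC1 against non-targeting, 6 µl and 18 µl, the count (1407, 691 and 717) was 2207, 1499 and 1459 with no background correction, 2288, 1569 and 1446 with the authors' values, 2368, 1653 and 1547 with trend and robust settings, 787, 277 and 385 without the filter on dim probes, and 149, 152 and 160 with a 2-fold threshold. Median scaling gave 2528 and 2985 for the first 2, 121 for 18 against 6 µl and 2 for the volume-dependent effect, and array weights gave 1292 at 6 µl. The cause was not tested, except that more probes tested raise the adjusted p and the 2-fold threshold removes smaller changes by construction. Leaving out each array in turn, the counts ranged from 155 (without non-targeting replicate 1) to 1434, from 18 (without STC1 6 µl replicate 2) to 887 at 6 µl, from 89 (without STC1 18 µl replicate 2) to 393 at 18 µl, and from 0 to 1 for 18 against 6 µl and for the volume-dependent effect, which has no value without either non-targeting array. Fewer arrays give less precision. Of 7 lists called by camera, 4 (without non-targeting replicate 1) to 7 remained in number, and 0 passed with an estimated correlation and 2 with fry, the unfolded protein and matrix lists.

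The replicate numbers are not shown to pair the samples: deviations of same-numbered arrays correlated at -0.02, -0.11 and 0.00 between groups. With the replicate number as a replicate block the counts were 1295, 615 and 608, with 0 for 18 against 6 µl and 7 lists. With the non-targeting numbers exchanged they were 1105 overall and 476 at 18 µl.

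Among the 24 largest changes, Rnase4, Phactr1, Slc44a3, Apol9a and Chac1 did not pass without non-targeting replicate 1 or without replicate 2, Bdh2 without non-targeting replicate 2, Phactr1 and Prl2c2 without STC1 6 µl replicate 2, and Prl2c2 without STC1 6 µl replicate 1 or STC1 18 µl replicate 2, with adjusted p between 0.0507 and 0.0915. Signal over background limits a part of the calls: 95 of the 1407 probes were below background on every array of 1 virus.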

Other observations

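The genes in this part lie outside the naming rule and were chosen after their values were seen. Hif1a, the oxygen-regulated subunit of the hypoxia-inducible factor, fell 2.78-fold with STC1 shRNA (log2 difference -1.47, SE 0.15, adjusted p = 0.0025, n = 4 against 2). It was above background on all 6 arrays and had no second tested probe. Hk1, a hexokinase, fell 2.19-fold and Slc6a8, the creatine transporter gene, 2.21-fold. Phex, an endopeptidase of phosphate regulation, fell 2.73-fold, Cyp24a1, the vitamin D hydroxylase, 2.56-fold, and Ano1, a calcium-activated chloride channel, 2.69-fold. Aqp1, a water channel, rose 2.05-fold with 2 further probes called the same way, and Mt2, a metallothionein, rose 2.05-fold.

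Osmr, the oncostatin M receptor, was 2.39-fold higher and Il27ra, an interleukin receptor subunit, 2.09-fold higher. Uba7, the enzyme that activates the ubiquitin-like protein of the interferon response, rose 2.11-fold, Apol9b 1.97-fold (a near-identical relative of Apol9a, so which of them its probe read is uncertain), the peptide transporter gene Tap2 1.88-fold and Samd9l 1.85-fold. Aldh1l2, a mitochondrial folate enzyme, fell 2.35-fold with a second probe called the same way, and Nupr1, a stress-induced nuclear protein, 1.96-fold. Has2, a hyaluronan synthase, fell 2.14-fold and the histone gene H2ax 2.03-fold. The SEs of these 18 log2 differences lay between 0.11 and 0.26 and their adjusted p-values between 0.00121 and 0.022. Of the 18 genes, 12 passed without non-targeting replicate 1 (not Cyp24a1, Samd9l, Nupr1, Hk1, Mt2 or Has2) and 15 without non-targeting replicate 2 (not Cyp24a1, Samd9l or Hk1). Without STC1 6 µl replicate 2 16 passed (not Samd9l or Mt2), and 17 passed without STC1 18 µl replicate 1 (not Cyp24a1) and without STC1 18 µl replicate 2 (not Hk1).

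The probe whose arrays fell furthest apart into 2 sets has no gene name here and followed neither virus nor volume. Its normalised log2 intensity was 12.20 on non-targeting replicate 1 and 12.35 on STC1 6 µl replicate 2, and between 5.35 and 6.10 on the other 4 arrays. It is also the unnamed probe given above for the volume-dependent effect without STC1 6 µl replicate 2. Leaving out that array left non-targeting replicate 1 as its only high array, with a difference of 7.16 between the STC1 effects. The largest gap between its sorted values, 6.11, compares with 3.01 for the next probe, which reads Tmsb10 and separates the viruses.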
